A study of Mus musculus and Homo sapiens with 36 samples.

How the data were processed

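Poly(A)-selected, strand-specific RNA-seq libraries were made from Hep3B cells (12 libraries, 50-base reads) and from mouse liver (24 libraries, 2 reads of 50 bases per fragment). Per the submitters' processing notes, FastQC, cutadapt, HISAT2, featureCounts and DESeq2 were used with the genome builds hg38 and mm10. Versions, settings and the strand setting of counting are not given in the sources used here, so reads of a gene and of an overlapping gene on the other strand may not be told apart. For each system the authors deposited 1 table of variance-stabilised values, which are on a log2 scale and have 1 floor shared by all libraries. The cell table held 28395 genes, of which 8996 lay at the floor in all 12 libraries and 614 had no symbol, and the mouse table held 18095 genes.

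The floors lay at 5.37 in cells and 5.75 in liver. Inverting the transformation from its floor gave whole reads, within 0.05, for 100% of the values of every library. These recovered reads gave the depth, the normalised reads and the endothelial permutation tests, and other main tests used the deposited values. A value 1 unit above the floor corresponds to 20.7 normalised reads in cells and 26.9 in liver. The scale is flattened there, so that a doubling from 10 reads appears as only 0.28 and 0.25 units, and the log2 changes understate the change of genes with few reads. The 10 genes with most reads held 5.71 to 6.36% of the reads of a cell library and 16.2 to 20.2% of those of a liver library. Mitochondrially encoded genes held 2.32 to 3.20% and 4.30 to 6.64%.

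Groups came from the labels. These number the cell libraries as biological replicates without saying that they came from separate cultures, so their p-values measure only the spread between these samples, which may be technical. No library repeated another: the lowest chi-square per gene between libraries of a group was 1.82 in cells and 17.0 in liver. Genes with a mean at least 1 unit above the floor were tested, 12260 in cells and 12636 in liver. In each system limma 3.58.1 (R 4.3.3, statmod 1.5.0) fitted 1 mean per group over all libraries, with an intensity-dependent prior variance and 8 and 20 residual degrees of freedom. The 8 contrasts were 5 between pairs of groups, the interaction and the 2 main effects, each the mean of the effects on both backgrounds. Tests were 2-sided with Benjamini-Hochberg adjustment within a contrast, and a call means an adjusted p under 0.05.

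Lists of pathway and cell type genes (28 for cells, 46 for liver, of which 43 had at least 5 genes measured) were fixed before the data were examined, as were the contrasts, the filter, the naming rule and most alternatives to be tried. Each list was compared with the other genes by limma's camera at a preset correlation of 0.01, with the p adjusted over the 224 and 344 tests of a system. Camera with an estimated correlation and fry were the alternatives. The mitochondrially encoded list was matched by the symbols used in the tables, a change made after they were read.

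Named genes followed a rule. For a pair of groups it takes up to 6 genes with the largest rises and 6 with the largest falls that were called, had a group mean at least 3 units above the floor, and did not overlap between groups (cells) or had at least 5 of 6 libraries of each group on their own side of the midpoint (liver). Predicted, clone-named, small RNA, receptor-segment and pseudogene symbols were passed over. It adds up to 4 members with the smallest p of each called list, 2 of other lists described, a set of genes of interest allowed whatever their values, and up to 4 genes each way for the interaction and main effects, with no condition on single libraries. The genes printed are a choice from those the rule yields, made with their values in view. Some genes that the rule yields are not reported here. Coordinates are those of a RefSeq table of GRCm38.p6, the assembly behind mm10.

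The alternatives were no filter and a filter at 2 units, a prior variance without the trend or made robust, quantile normalisation, median centring, array weights, a replicate block, leaving out each library, log2 of normalised reads plus 1, voom on the recovered reads, and only the 2 groups compared. No scaling moved the median change of all genes by more than 0.02. Added after the data were seen was a fit without 3 mouse libraries together, those with the highest absolute score on principal components 2, 4 and 3. Replicate numbers were checked for pairing by the correlation of deviations from the group means. In the livers given vehicle and both drugs every same-numbered pair lay above 0.1 (0.112 to 0.435, against -0.732 to 0.548 for other pairs), although a library's own number was not always its best match, and a fit of these 2 groups with the block was added.

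On simulated data, lenvatinib against vehicle in cells recovered 64, 92, 95.9 and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold, and called 10 of 11883 unchanged genes. In liver the shares were 26, 67.3, 76.6 and 95.9%, with 8 of 12210 unchanged genes called, and for the interaction in liver 8, 44, 55.1 and 89.6%. These figures describe the simulation only. Another split of the real lenvatinib and vehicle livers called 376 genes. Other splits of the libraries, at most 100 per result, were refitted in the same way. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.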

Results

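RNA-seq of 36 libraries from 2 systems was compared. In the first, Hep3B human hepatocellular carcinoma cells were exposed for 9 h to DMSO vehicle, 1 mM salicylic acid, 100 nM lenvatinib or both compounds, with 3 libraries per group. In the second, non-tumour liver was taken from male C57BL/6J mice in a model that joins a Western diet with weekly CCl4 (0.32 µg/g) and produces fatty liver, inflammation and fibrosis. These mice received vehicle, salsalate (300 mg/kg/day), lenvatinib (2.5 mg/kg/day) or both on 6 days of each of the last 6 weeks of a 30-week protocol, with 6 livers per group. Salsalate is a prodrug that the body splits into salicylic acid, and lenvatinib inhibits the kinases of the VEGF, FGF and PDGF-alpha receptors, KIT and RET. The labels call the compound given to the cells salicylic acid in the dose and salsalate in the titles, and it is called salicylate here. The series asks how salsalate and lenvatinib act together in liver cancer that arises on metabolic fatty liver disease.

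Each library held 16.4 to 28.8 M assigned reads in the cells (median 19.4) and 19.4 to 42.4 M in the mice (median 25.7). The salsalate livers were sequenced more deeply, at 31.4 ± 6.08 M reads (mean ± SD, n = 6), than the vehicle livers at 23.5 ± 3.03, the lenvatinib livers at 24.1 ± 2.56 and the combination livers at 26.9 ± 2.48. Cell libraries of a group lay close together on the first 2 principal components, which held 46.5% and 23.4% of the variance. Mouse libraries of a group overlapped those of other groups. Lenvatinib library 2 had the highest score on principal component 2 (39.4), combination library 6 on component 3 (27.2) and lenvatinib library 5 the lowest on component 4 (-21.7), and these are the 3 libraries said here to stand apart. By root mean square deviation from its group, lenvatinib library 1 (0.376) and combination library 2 (0.367) lay farther out than lenvatinib library 5 (0.332) and combination library 6 (0.314). As the median over a list of each gene's log2 deviation from the mean of the group's other libraries, lenvatinib library 2 lay at -2.37 for pericentral hepatocyte genes and -1.53 for fatty acid and triglyceride synthesis. Lenvatinib library 5 lay at 1.33 for the periportal and gluconeogenic list and 0.91 for interferon response genes. Combination library 6 lay at 1.98 for 6 neutrophil markers, 1.26 for B and plasma cell markers, 1.13 for cholesterol genes and 0.94 for acute phase genes.

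**Figure D1:**
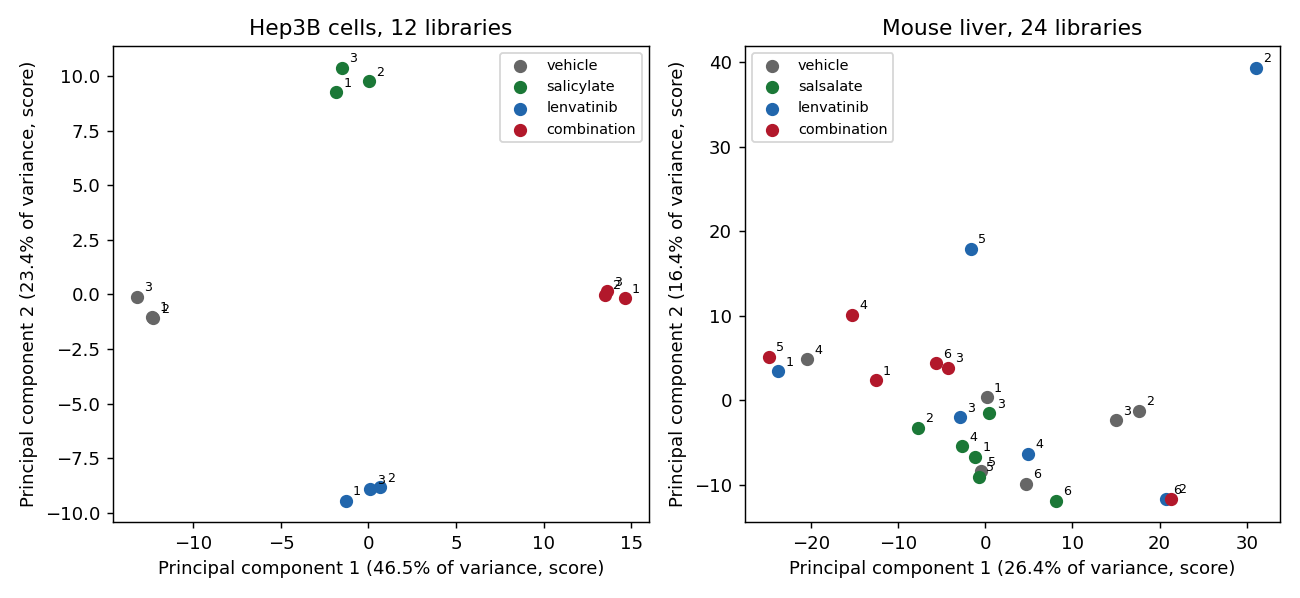
Scores of each library on the first and second principal components for 12 cell libraries (left) and 24 mouse liver libraries (right), coloured by treatment and numbered by replicate, with the percentage of variance on each axis. The 4 cell groups lie apart from each other, whereas the mouse groups overlap and lenvatinib library 2 lies at the top with a second score of 39.4.

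Salicylate alone was first set against vehicle in Hep3B cells. The genes that rose furthest were led by CHAC1, a glutathione-degrading enzyme under the transcription factor ATF4, which went from 198 ± 30.3 to 749 ± 13.4 normalised reads (mean ± SD, n = 3), a log2 change of 1.60 ± 0.06 (SE, adjusted p = 2.43e-18). ANGPTL8, an insulin-induced lipoprotein lipase regulator (1.35 ± 0.05), AMZ1 (1.31 ± 0.05) and the lipid droplet protein PLIN4 (1.15 ± 0.04) also rose by over 1 unit. So did STC2 (1.14 ± 0.05), ADM2 (1.11 ± 0.07), NUPR1 (1.11 ± 0.04) and DDIT4 (1.09 ± 0.04), the last an inhibitor of mTORC1 signalling. Asparagine synthetase, ASNS, rose by 0.87 ± 0.04. The largest falls were smaller: the metallothionein MT1G was at -0.71 ± 0.07, the smooth-muscle actin-binding protein TAGLN at -0.63 ± 0.06, the keratin KRT80 at -0.62, HOXA3 at -0.59, the gap junction protein GJA1 at -0.57 and the thyroid hormone-inactivating enzyme DIO3 at -0.57. MT1G has near-identical family members, so its reads may be shared.

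With salicylate, of the 9 measured PPAR-alpha-induced lipid genes, 7 rose and 0 fell (the same adjusted over the list alone), and these included PLIN2 (0.99 ± 0.04), ANGPTL4 (0.65), FABP1 (0.54) and CREB3L3 (0.54). Their median was 0.54 (adjusted p = 5.16e-08 by camera and 0.00837 with an estimated correlation). The fatty acid oxidation regulators CPT1A and PDK4 rose by 0.52 and 0.58. In the fatty acid and triglyceride synthesis list (18 genes) 5 rose and 0 fell (the same adjusted over the list alone). Their median was 0.05 (adjusted p = 0.0415 by camera and 0.494 with an estimated correlation), a call lost without vehicle library 3 (adjusted p = 0.0933). GPAM (0.73) and MLXIPL (0.56) were among those that rose, SCD rose by 0.15, and FASN changed by 0.08 without passing (adjusted p = 0.106). The 21 ATF4 and integrated stress response genes went one way: 19 rose and 0 fell (20 and 0 adjusted over the list alone). Their median was 0.53 (adjusted p = 1.5e-32 by camera and 0.000390 with an estimated correlation). Among 17 endoplasmic reticulum chaperone and unfolded protein response genes 8 rose and 0 fell (the same adjusted over the list alone), with HERPUD1 at 0.71 and DNAJB9 at 0.52. Their median was 0.08 (adjusted p = 0.000125 by camera and 0.229 with an estimated correlation). CYP1A1 and TIPARP, both induced by the aryl hydrocarbon receptor, rose by 0.74 and 0.33, and in the xenobiotic metabolism list (10 genes) 5 rose and 1 fell (the same adjusted over the list alone). Their median was 0.17 (adjusted p = 0.00595 by camera and 0.129 with an estimated correlation). Of 17 circadian clock genes 9 rose and 0 fell (the same adjusted over the list alone), PER3 (0.52) and TEF (0.41) among them. Their median was 0.17 (adjusted p = 0.0218 by camera and 0.178 with an estimated correlation). Of 18 hepatocyte identity genes 6 rose and 1 fell (7 and 2 adjusted over the list alone), with CEBPA at 0.33. Their median was 0.09 (adjusted p = 0.00367 by camera and 0.444 with an estimated correlation).

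In further lists more genes fell than rose with salicylate. Of 18 ribosome biogenesis genes 0 rose and 16 fell (the same adjusted over the list alone), with NOP56 at -0.38 and BOP1 at -0.23. Their median was -0.19 (adjusted p = 2.46e-10 by camera and 0.178 with an estimated correlation). Of 22 mitosis genes 1 rose and 16 fell (1 and 17 adjusted over the list alone), with PLK1 at -0.37 and AURKA at -0.28. Their median was -0.15 (adjusted p = 4.37e-08 by camera and 0.242 with an estimated correlation). Cytosolic ribosomal proteins (24 genes) behaved alike: 0 rose and 16 fell (0 and 17 adjusted over the list alone), RPL35 at -0.23 being an example. Their median was -0.10 (adjusted p = 5.07e-05 by camera and 0.444 with an estimated correlation). Of 26 oxidative phosphorylation genes 0 rose and 8 fell (0 and 9 adjusted over the list alone), CYC1 changing by -0.23. Their median was -0.08 (adjusted p = 0.00687 by camera and 0.444 with an estimated correlation). Among 10 heat shock genes 0 rose and 4 fell (the same adjusted over the list alone), with HSPB1 at -0.29. Their median was -0.11 (adjusted p = 0.0274 by camera and 0.444 with an estimated correlation), a call lost without salicylate library 3 (adjusted p = 0.0654). CCND1 fell by 0.22, whereas EGR1 rose by 0.56. The NF-kappaB and inflammatory list (15 genes) did not pass: 2 rose and 6 fell (2 and 7 adjusted over the list alone), with TNFAIP2 at -0.26 and the chemokine CCL20 at 0.53. Their median was -0.14 (adjusted p = 0.0858 by camera and 0.686 with an estimated correlation). In total 1795 genes rose and 1960 fell of 12260 tested, and 10 of them changed by at least 1 log2 unit.

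The genes that fell furthest with lenvatinib alone were led by IGFBP1, which went from 538 ± 21 to 128 ± 11.1 normalised reads (mean ± SD, n = 3), a log2 change of -1.61 ± 0.06 (SE, adjusted p = 1.55e-18), and the cytokine IL11 from 965 ± 105 to 265 ± 19.6, a change of -1.61 ± 0.07. The long-chain acyl-CoA synthetase ACSL5 (-1.50 ± 0.07), the scaffold protein AKAP12 (-1.25 ± 0.04), the collagen cross-linking enzyme LOXL2 (-1.25) and DIO3 (-1.16) fell by over 1 unit. Of 18 ERK pathway response genes 1 rose and 12 fell (the same adjusted over the list alone), and these included the immediate-early genes EGR1 (-0.67) and FOSL1 (-0.89), the feedback inhibitor SPRY4 (-0.61) and EPHA2 (-0.41). Their median was -0.28 (adjusted p = 1.1e-10 by camera and 0.0183 with an estimated correlation). DUSP6, another ERK feedback gene, did not pass (-0.03, adjusted p = 0.615). FGF19 fell by 0.40, PDGFB by 0.47 and CCND1 by 0.17.

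The genes that rose with lenvatinib were led by GPAM, which starts glycerolipid synthesis (0.86 ± 0.07), the bile acid receptor NR1H4 (0.84 ± 0.08), CHAC1 (0.76 ± 0.06), TP53INP1 (0.75), NUPR1 (0.71) and MLXIPL (0.69). Of 18 hepatocyte identity genes 14 rose and 0 fell (the same adjusted over the list alone), with CEBPA at 0.34 and ASS1 at 0.31. Their median was 0.19 (adjusted p = 4.56e-09 by camera and 0.178 with an estimated correlation). The ATF4 list (21 genes) again moved mainly upward: 14 rose and 2 fell (16 and 2 adjusted over the list alone), with the serine synthesis enzymes PSPH (0.62) and PSAT1 (0.41) among those that rose. Their median was 0.20 (adjusted p = 2.45e-10 by camera and 0.00908 with an estimated correlation). Of 19 beta-oxidation genes 7 rose and 1 fell (12 and 1 adjusted over the list alone), and CPT1A changed by 0.42. Their median was 0.10 (adjusted p = 0.00126 by camera and 0.215 with an estimated correlation). FASN did not pass (0.04, adjusted p = 0.448). CREB3L3 rose by 0.69 and FABP1 by 0.27, the latter call and that of ATP8 below being lost with a robust prior variance. Of 25 cholesterol genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), HMGCS1 at 0.20 and TM7SF2 at 0.34 being examples. Their median was 0.05 (adjusted p = 0.00603 by camera and 0.494 with an estimated correlation), and this call was lost without lenvatinib library 3 (adjusted p = 0.0882). Among 10 acute phase genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), with FGG at 0.37. Their median was 0.13 (adjusted p = 0.00905 by camera and 0.333 with an estimated correlation). XBP1 rose by 0.21 and HERPUD1 by 0.32.

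With lenvatinib, of 18 ribosome biogenesis genes 0 rose and 14 fell (0 and 15 adjusted over the list alone), with RRP12 at -0.30 and MYBBP1A at -0.28. Their median was -0.17 (adjusted p = 4.45e-10 by camera and 0.178 with an estimated correlation). Of 24 cytosolic ribosomal proteins 0 rose and 6 fell (0 and 7 adjusted over the list alone). Their median was -0.07 (adjusted p = 0.00130 by camera and 0.490 with an estimated correlation). RPL10A (-0.11) was among those that fell, a call lost without any of vehicle libraries 1 and 3 and lenvatinib library 1 and under quantile normalisation. In the YAP and TGF-beta response list (12 genes) 0 rose and 5 fell (the same adjusted over the list alone), with CCN1 at -0.64, AXL at -0.85 and a mean over the list of -0.28. Their median was -0.04 (adjusted p = 0.000307 by camera and 0.361 with an estimated correlation). Of 15 NF-kappaB and inflammatory genes 0 rose and 5 fell (the same adjusted over the list alone), CSF1 (-0.50) and CXCL8 (-0.40) among them. Their median was -0.06 (adjusted p = 0.0146 by camera and 0.535 with an estimated correlation), a call lost without vehicle library 3 (adjusted p = 0.126). The 13 mitochondrially encoded transcripts differed less evenly: 0 rose and 4 fell (0 and 6 adjusted over the list alone), ATP8 changing by -0.30. Their median was -0.15 (adjusted p = 0.00173 by camera and 0.565 with an estimated correlation), and the call was lost without lenvatinib library 1 (adjusted p = 0.177). CDC25C rose by 0.34. In total 1309 genes rose and 1510 fell, 7 of them by at least 1 log2 unit.

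Cells given both compounds differed most from vehicle. CHAC1 went from 198 ± 30.3 to 1447 ± 63.8 normalised reads (mean ± SD, n = 3), a log2 change of 2.48 ± 0.06 (SE, adjusted p = 1.35e-23), followed by NUPR1 (1.87 ± 0.04), ADM2 (1.77 ± 0.07), STC2 (1.63 ± 0.05), the glycine transporter SLC6A9 (1.46 ± 0.09), DDIT4 (1.45 ± 0.04) and ASNS (1.35). Of the 21 ATF4 genes 19 rose and 1 fell (20 and 1 adjusted over the list alone). Their median was 1.11 (adjusted p = 7.78e-25 by camera and 0.000776 with an estimated correlation). Of 17 endoplasmic reticulum stress genes 13 rose and 0 fell (the same adjusted over the list alone), with HERPUD1 at 1.08 and XBP1 at 0.48. Their median was 0.17 (adjusted p = 3.74e-05 by camera and 0.211 with an estimated correlation). Lipid genes that rose included GPAM (1.31), MLXIPL (1.19), CREB3L3 (1.06), CPT1A (0.84) and PLIN2 (0.43), while FASN did not pass (0.06, adjusted p = 0.176). In the PPAR-alpha list (9 genes) 8 rose and 0 fell (the same adjusted over the list alone). Their median was 0.47 (adjusted p = 1.73e-05 by camera and 0.0183 with an estimated correlation). Hepatocyte identity genes (18) rose more often than they fell: 16 rose and 1 fell (the same adjusted over the list alone), with CEBPA at 0.58. Their median was 0.20 (adjusted p = 1.93e-06 by camera and 0.229 with an estimated correlation).

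The genes that fell furthest with both compounds were AKAP12 (-1.74 ± 0.04), ACSL5 (-1.74 ± 0.07), DIO3 (-1.68), GJA1 (-1.66), IL11 (-1.52) and LOXL2 (-1.50). Of 18 ribosome biogenesis genes 0 rose and 18 fell (the same adjusted over the list alone), NOP56 (-0.57) and MYBBP1A (-0.52) among them. Their median was -0.44 (adjusted p = 6.93e-14 by camera and 0.126 with an estimated correlation). Of 18 ERK response genes 1 rose and 14 fell (2 and 15 adjusted over the list alone), with FOSL1 at -1.11, SPRY4 at -0.78 and PHLDA1 at -0.61, while EGR1 changed by -0.20 (adjusted p = 0.000519). Their median was -0.30 (adjusted p = 1.36e-06 by camera and 0.0807 with an estimated correlation). Inflammatory genes fell in number too: of 15 NF-kappaB genes 1 rose and 12 fell (the same adjusted over the list alone), led by the macrophage growth factor CSF1 (-0.90) and the adhesion molecule ICAM1 (-0.54). Their median was -0.31 (adjusted p = 7.63e-05 by camera and 0.361 with an estimated correlation). Of 22 mitosis genes 2 rose and 16 fell (the same adjusted over the list alone), with PLK1 at -0.34 and, against the direction of the list, CDC25C at 0.44. Their median was -0.15 (adjusted p = 0.00330 by camera and 0.485 with an estimated correlation). Among 24 cytosolic ribosomal proteins 0 rose and 18 fell (the same adjusted over the list alone), RPL35 being at -0.27. Their median was -0.11 (adjusted p = 0.000784 by camera and 0.485 with an estimated correlation). Heat shock genes (10) were lower: 1 rose and 8 fell (the same adjusted over the list alone), HSP90AB1 at -0.32. Their median was -0.26 (adjusted p = 0.00673 by camera and 0.359 with an estimated correlation). Of 23 glycolysis and hypoxia genes 4 rose and 15 fell (the same adjusted over the list alone), with LDHA at -0.32 and ENO1 at -0.31 but VEGFA at 0.50. Their median was -0.24 (adjusted p = 0.0197 by camera and 0.454 with an estimated correlation). AXL fell by 0.94. The Wnt target LGR5 fell by 0.60, CCND1 by 0.53 and MKI67 by 0.18, the last a call lost under quantile normalisation. In total 2994 genes rose and 3415 fell, 48 of them by at least 1 log2 unit.

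**Figure D2:**
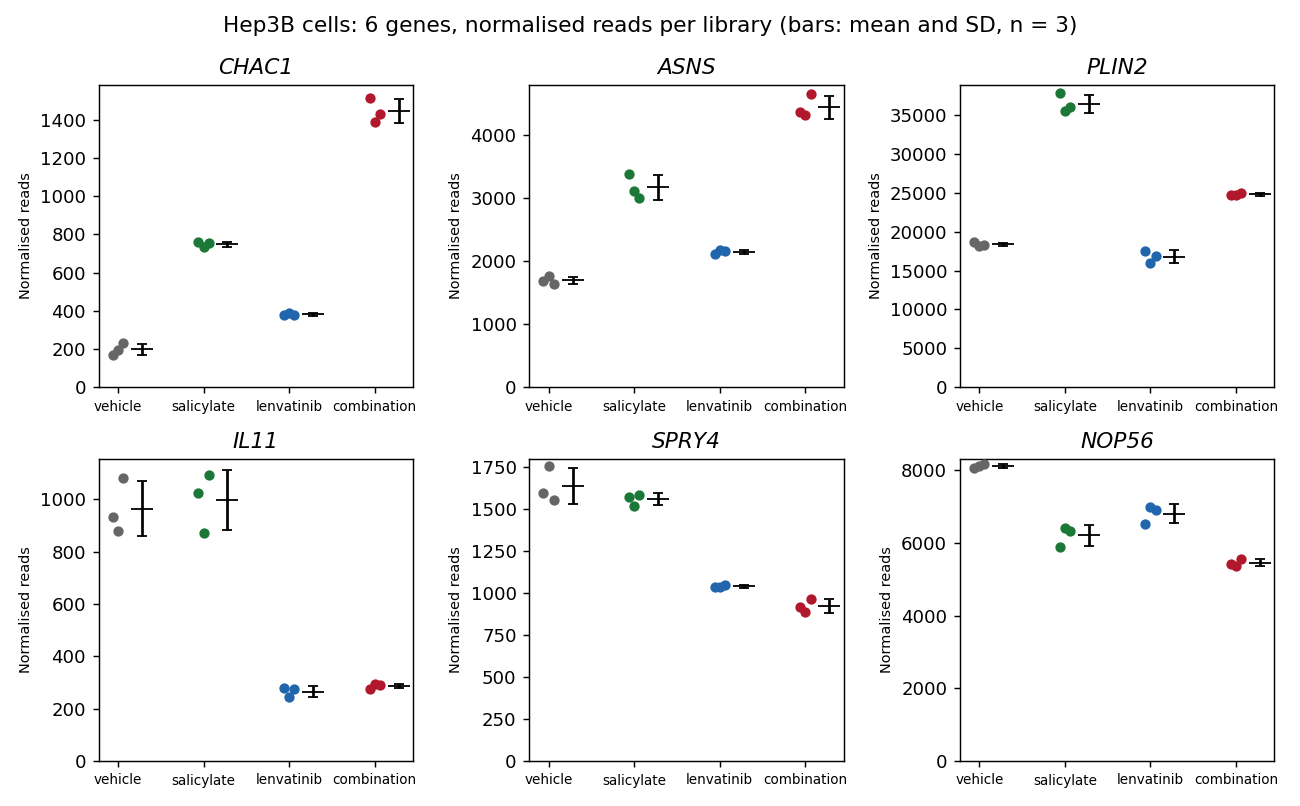
Normalised reads of 6 genes in each Hep3B library (points, n = 3 per group) by treatment, with the group mean and SD beside them. CHAC1 and ASNS were highest with both compounds, PLIN2 was highest with salicylate alone, and IL11 and SPRY4 were lower in both lenvatinib groups.

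Adding salicylate to lenvatinib was compared with lenvatinib alone. CHAC1 again led the rises at 1.73 ± 0.06 (SE, adjusted p = 4.29e-19). STC2 rose by 1.26 ± 0.05, DDIT4 by 1.20, ADM2 by 1.18, SLC6A9 by 1.17, AMZ1 by 1.16, NUPR1 by 1.16 and ASNS by 1.02. Of the 21 ATF4 genes 21 rose and 0 fell (the same adjusted over the list alone). Their median was 0.72 (adjusted p = 1.59e-39 by camera and 0.000390 with an estimated correlation). Of the 9 PPAR-alpha genes 7 rose and 0 fell (8 and 0 adjusted over the list alone), the lipid droplet proteins PLIN2 (0.56) and PLIN5 (0.45) included. Their median was 0.37 (adjusted p = 1.81e-05 by camera and 0.0183 with an estimated correlation). HERPUD1 rose by 0.76, CYP1A1 by 0.72, EGR1 by 0.47, PER3 by 0.46, GPAM by 0.45 and HNF4A by 0.24. GJA1 (-0.89), the growth factor TGFB2 (-0.73), TAGLN (-0.71), KRT80 (-0.65), CXCL5 (-0.65), MCC (-0.63) and LGR5 (-0.53) fell. Of 18 ribosome biogenesis genes 0 rose and 18 fell (the same adjusted over the list alone), with NOP56 at -0.31. Their median was -0.25 (adjusted p = 2.63e-13 by camera and 0.129 with an estimated correlation). Of 22 mitosis genes 0 rose and 18 fell (the same adjusted over the list alone), with PLK1 at -0.33. Their median was -0.17 (adjusted p = 2.46e-09 by camera and 0.215 with an estimated correlation). ICAM1 fell by 0.34 and TNFAIP3 by 0.38. HSP90AB1 fell by 0.31. In total 1849 genes rose and 2312 fell.

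Adding lenvatinib to salicylate was compared with salicylate alone. IGFBP1 fell by 1.81 ± 0.06 (SE, adjusted p = 7.36e-20), and ACSL5 (-1.79), IL11 (-1.56), AKAP12 (-1.53), LOXL2 (-1.26) and SYT12 (-1.25) fell by over 1 unit. Of 18 ERK genes 0 rose and 16 fell (the same adjusted over the list alone), with EGR1 at -0.76, SPRY4 at -0.71 and JUNB at -0.45. Their median was -0.31 (adjusted p = 1.53e-13 by camera and 0.0109 with an estimated correlation). Of 15 NF-kappaB genes 1 rose and 7 fell (1 and 8 adjusted over the list alone), CCL20 at -0.67 and CXCL8 at -0.61. Their median was -0.12 (adjusted p = 0.000270 by camera and 0.406 with an estimated correlation). Ribosome biogenesis (18 genes) was lower here too: 0 rose and 17 fell (the same adjusted over the list alone), GNL3 at -0.37. Their median was -0.24 (adjusted p = 5.48e-12 by camera and 0.149 with an estimated correlation). PLIN2, which salicylate alone had raised, fell by 0.56. CHAC1 (0.88 ± 0.06), PRRT1B (0.82), NUPR1 (0.76), TP53INP1 (0.71), SLC26A1 (0.69), ADM2 (0.66) and the mitochondrial enzyme PCK2 (0.63) rose, and of the 21 ATF4 genes 19 rose and 1 fell (19 and 2 adjusted over the list alone). Their median was 0.36 (adjusted p = 1.25e-17 by camera and 0.00220 with an estimated correlation). ACACB rose by 0.68, ECI1 by 0.26 and XBP1 by 0.25. In total 1677 genes rose and 2095 fell.

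Whether the compounds together did more or less than the sum of each was tested by the interaction. The ATF4 list (21 genes) exceeded the sum: 3 lay above and 0 below (9 and 0 adjusted over the list alone). Their median was 0.15 (adjusted p = 3.34e-11 by camera and 0.00837 with an estimated correlation). Over all genes tested, the 3 members that passed were PCK2 (0.31), the serine synthesis enzyme PHGDH (0.30) and the amino acid transporter subunit SLC3A2 (0.20). PLIN2 lay below the sum at -0.43 ± 0.05 (SE, adjusted p = 1.15e-05) and CCL20 at -0.37. Other genes below the sum were TNFSF4 (-0.55), the Notch modifier LFNG (-0.53), the ciliary transcription factor FOXJ1 (-0.50) and LCN10 (-0.47), and others above it were PABPC1L (0.52), MT1G (0.51), AKNA (0.46) and SH3BP2 (0.39). The PPAR-alpha list (9 genes) lay below the sum: 0 lay above and 1 below (0 and 2 adjusted over the list alone). Their median was -0.07 (adjusted p = 0.0131 by camera and 0.173 with an estimated correlation). The ERK list (18 genes), which lenvatinib lowered, lay further down than the sum: 0 lay above and 0 below (0 and 3 adjusted over the list alone). Their median was -0.11 (adjusted p = 0.00124 by camera and 0.211 with an estimated correlation). In the NF-kappaB list (15 genes) 0 lay above and 1 below (0 and 4 adjusted over the list alone). Their median was -0.08 (adjusted p = 0.00154 by camera and 0.444 with an estimated correlation). Of 12260 genes, 35 lay above and 95 below the sum, and 32 above and 187 below after median centring. Without the variance trend the total of 130 was 22, and the calls of PCK2, PHGDH, SLC3A2, CCL20, MT1G, SH3BP2, PABPC1L and LCN10 were lost. With no filter it was 61, and those of SLC3A2, PABPC1L and LCN10 were lost. The 130 genes became 33, 40 and 54 without combination libraries 3, 2 and 1, 42, 47 and 52 without vehicle libraries 3, 1 and 2, 63 and 80 without lenvatinib libraries 3 and 1, and 65 without salicylate library 1, but 204 without salicylate library 3 and 781 without lenvatinib library 2. The calls of PABPC1L, LCN10 and SLC3A2 were lost without any 1 of 9, 8 and 10 libraries, those of PHGDH, PCK2 and MT1G without any 1 of 4, 3 and 2, and that of SH3BP2 without combination library 1.

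Averaged over both backgrounds, 2697 genes rose and 3085 fell with salicylate, led by CHAC1 (1.67), AMZ1 (1.24), STC2 (1.20) and ANGPTL8 (1.18) and, downward, GJA1 (-0.73), TAGLN (-0.67), TGFB2 (-0.64) and KRT80 (-0.64). With lenvatinib 2285 rose and 2538 fell, led by CHAC1 (0.82), NUPR1 (0.74), TP53INP1 (0.73) and NR1H4 (0.72) and, downward, IGFBP1 (-1.71), ACSL5 (-1.64), IL11 (-1.58) and AKAP12 (-1.39). The salicylate effects without and with lenvatinib share no library and correlated across genes at r = 0.736 (rho = 0.686), and 2299 of the 2313 genes called in both moved the same way, against 640.3 for independent lists. The lenvatinib effects without and with salicylate correlated at r = 0.752 (rho = 0.646), and 1852 of 1861 shared calls moved the same way, against 437.1. Genes are not independent replicates, so no p is given for these correlations. Of the 91 list calls over the 8 contrasts in cells, 15 held with an estimated correlation, all in the ATF4, PPAR-alpha and ERK lists.

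**Figure D3:**
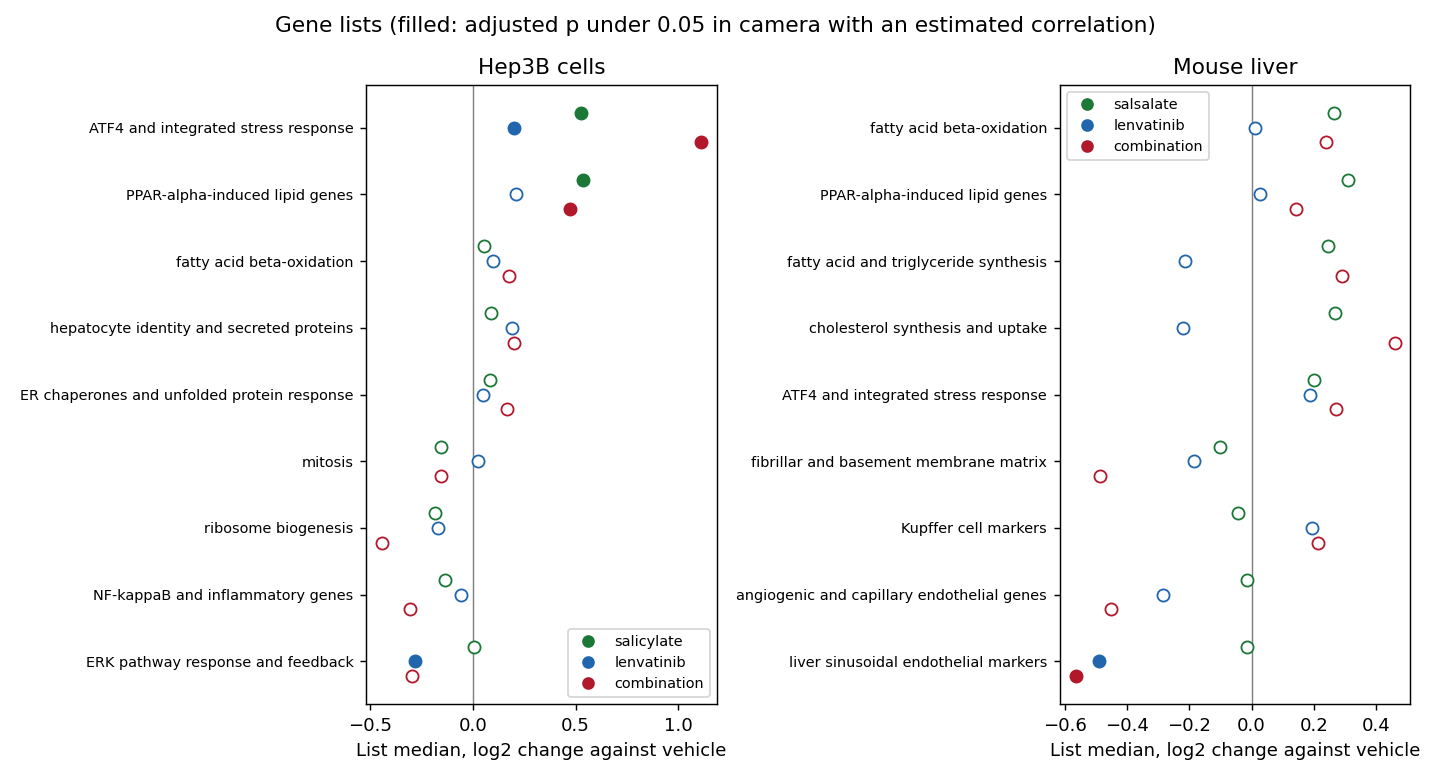
Median log2 change against vehicle of 9 gene lists in Hep3B cells (left) and 9 in mouse liver (right) for each treatment, with filled points where camera passed with an estimated correlation. The ATF4 list reached its highest median, 1.11, in cells given both compounds, and the sinusoidal endothelial list lay at -0.49 and -0.57 in the livers given lenvatinib and both compounds.

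In the mouse livers, the genes that rose with salsalate alone were led by Cyp4a14, a fatty acid omega-hydroxylase (chromosome 4, 115486200 to 115496158 in GRCm38.p6, protein coding), which went from 5536 ± 3417 to 84042 ± 9136 normalised reads (mean ± SD, n = 6), a log2 change of 4.16 ± 0.51 (SE, adjusted p = 0.000353), with all 6 salsalate livers beyond the midpoint of the groups. Its neighbour Cyp4a10 (115518287 to 115533649) rose by 2.56 ± 0.39, Cyp4a31 by 1.90 ± 0.32 and Cyp4a32 by 0.98 ± 0.16. These near-identical copies may share reads, so their values are uncertain. Ehhadh, the peroxisomal bifunctional enzyme (chromosome 16, 21761285 to 21787834), rose by 2.13 ± 0.31, the retinol saturase Retsat by 1.44 ± 0.21 and the mitochondrial trifunctional protein subunits Hadha and Hadhb by 0.36 ± 0.06 and 0.34. Eci1 (0.52), the acyl-CoA thioesterase Acot2 (0.77) and the pantetheinase Vnn1 (0.58) rose as well. The gene that fell was Cfhr4, a complement factor H relative (-0.54 ± 0.11, adjusted p = 0.0295).

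Of 20 beta-oxidation genes 4 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was 0.27 (adjusted p = 2.47e-21 by camera and 0.0896 with an estimated correlation). Of 15 PPAR-alpha-induced lipid genes 4 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.31 (adjusted p = 7.47e-09 by camera and 0.113 with an estimated correlation). Cpt1a did not pass (-0.26, adjusted p = 0.890). Camera also placed other lists above or below the rest without single members passing. The fatty acid and triglyceride synthesis list (20 genes) had a median of 0.25, with Fasn at 0.64, Acly at 0.86 and Pnpla3 at 1.15. Adjusted p was 0.000234 by camera and 0.982 with an estimated correlation. The cholesterol list (25 genes) had a median of 0.27, with Hmgcs1 at 0.45 and Insig1 at 0.41. Adjusted p was 1.78e-05 by camera and 0.982 with an estimated correlation. The ATF4 list (20 genes) had a median of 0.20, Atf4 itself being at 0.29. Adjusted p was 0.000784 by camera and 0.764 with an estimated correlation. The periportal and gluconeogenic list (15 genes) lay at -0.26, with Sds at -0.68. Adjusted p was 0.00161 by camera and 0.982 with an estimated correlation. Without 1 library, vehicle 5, salsalate 1 and vehicle 4, the medians of the synthesis, PPAR-alpha and periportal lists were 0.38, 0.16 and -0.17. The fibrosis gene Col1a1 (-0.18) and the endothelial receptor Kdr (-0.04) did not pass, both at adjusted p = 0.999. In total 14 genes rose and 1 fell of 12636, or 9 genes without vehicle library 2 and 9 without salsalate library 2, 25 without lenvatinib library 2 and 28 without the 3 libraries that stood apart. The calls of Hadhb, Eci1, Vnn1, Acot2 and Cfhr4 were lost without any 1 of 14, 11, 9, 7 and 7 libraries, those of Eci1 and Vnn1 also with a replicate block, Vnn1 under quantile normalisation, Hadhb with no filter, and Hadhb and Cyp4a31 with voom.

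Lenvatinib alone lowered transcripts of the sinusoidal endothelial list, which also holds pan-endothelial genes such as Pecam1 and Cdh5. Kdr, which encodes VEGF receptor 2 (chromosome 5, 75932827 to 75979072), went from 778 ± 98.3 to 374 ± 50.9 normalised reads (mean ± SD, n = 6), a log2 change of -0.89 ± 0.12 (SE, adjusted p = 0.000556). The sinusoidal lectin Clec4g (chromosome 8, 3707066 to 3720695) changed by -0.94 ± 0.18, Dnase1l3 by -0.88 ± 0.14, Oit3 by -0.85 ± 0.14, the lipase anchor Gpihbp1 by -0.84 ± 0.12, the endothelial phosphatase Ptprb by -0.75 ± 0.11 and the iron-regulating ligand Bmp2 by -0.74 ± 0.11. Of 22 sinusoidal endothelial genes 0 rose and 11 fell (0 and 17 adjusted over the list alone). Their median was -0.49 (adjusted p = 4.2e-37 by camera and 0.00116 with an estimated correlation). Of 15 angiogenic and capillary genes 0 rose and 0 fell (0 and 6 adjusted over the list alone), with Esm1 at -1.11 (adjusted p = 0.177) and Dll4 at -0.53. Their median was -0.29 (adjusted p = 5.99e-06 by camera and 0.553 with an estimated correlation). Without vehicle library 2 it was -0.19. Of 14 genes for lenvatinib's target kinases and their ligands 0 rose and 1 fell (the same adjusted over the list alone). Their median was -0.20 (adjusted p = 0.0131 by camera and 0.634 with an estimated correlation), a call lost without lenvatinib library 1 (adjusted p = 0.0963), and Flt1 was at -0.28 (adjusted p = 0.468). The median was -0.08 without that library, -0.11 without lenvatinib library 5 and -0.06 without the 3 libraries that stood apart.

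The 3 genes that rose were Mif (0.47 ± 0.10), Gm6402 (0.44) and Chchd2-ps (0.50), of which the last 2 lie outside the naming rule and were chosen after their values were seen, and all may share reads with close copies. Further lists passed camera with 0 members passing (0 adjusted over each list alone). The cholesterol list (25 genes) had a median of -0.22, with Fdps at -0.61. Adjusted p was 0.000494 by camera and 0.982 with an estimated correlation. This call was lost without lenvatinib library 2 (adjusted p = 0.276). Its median was -0.06 without that library, -0.34 without lenvatinib library 6 and -0.006 (adjusted p = 0.681) without the 3 libraries that stood apart. The pericentral list (15 genes) had a median of -0.22, with Glul at -0.61 (0.13 without the 3 libraries that stood apart). Adjusted p was 0.0489 by camera and 0.982 with an estimated correlation, a call lost without any 1 of 13 libraries. Without lenvatinib library 2, itself at -2.37, the direction of the list turned (adjusted p = 0.213). The glycolysis and hypoxia list (22 genes) had a median of 0.16, with Aldoa at 0.28. Adjusted p was 0.00435 by camera and 0.947 with an estimated correlation. The matrix list (26 genes) had a median of -0.18, with Col1a1 at -0.31. Adjusted p was 0.0216 by camera and 0.982 with an estimated correlation. The call was lost without any of vehicle libraries 2, 3 and 6 and lenvatinib libraries 1, 2 and 5. Without lenvatinib library 1 the glycolysis, matrix and pericentral medians were 0.25, -0.11 and -0.33, and without the 3 that stood apart the last 2 were -0.05 (adjusted p = 0.899) and 0.23. The first was 0.10 without lenvatinib library 5, the second -0.33 and -0.30 without lenvatinib library 6 and vehicle library 4, and the last -0.36 without lenvatinib library 3. In total 3 genes rose and 34 fell, or 60 changed without lenvatinib library 6, and the call of Mif was lost without any 1 of 9 libraries, without the 3 that stood apart, with array weights, with only these 2 groups and under quantile normalisation.

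Livers given both drugs were also set against vehicle. Cyp4a14 (3.96 ± 0.51, adjusted p = 9.44e-05), Cyp4a10 (2.35 ± 0.39), Cyp4a31 (2.19 ± 0.32), Ehhadh (1.97 ± 0.31) and the thioesterases Acot1 (1.42 ± 0.28) and Acot2 (0.89) rose. Acot1 and Acot2 are close copies that may share reads. Hadha (0.36) and Eci1 (0.48) rose, as did the nicotinic receptor subunit Chrna4 (1.84 ± 0.43) and the stress-induced mTORC1 inhibitor Sesn2 (0.55). Kdr went from 778 ± 98.3 to 355 ± 116 normalised reads (mean ± SD, n = 6), a log2 change of -0.98 ± 0.12 (SE, adjusted p = 5.3e-05), and the Fc receptor Fcgr2b (chromosome 1, 170960558 to 170976071), a sinusoidal scavenger, changed by -0.86 ± 0.09. Gpihbp1 (-0.93), Clec4g (-0.87), Mmrn2 (-0.77), Bmp2 (-0.73), Ptprb (-0.73), Esm1 (-1.41), the Notch ligand Dll4 (-0.67), Igfbp3 (-0.60), the KIT ligand Kitl (-0.49) and the lipid droplet gene Plin4 (-1.50 ± 0.31) fell. Of 22 sinusoidal endothelial genes 0 rose and 14 fell (0 and 19 adjusted over the list alone). Their median was -0.57 (adjusted p = 1.91e-32 by camera and 0.00207 with an estimated correlation). Of 15 angiogenic genes 0 rose and 3 fell (0 and 9 adjusted over the list alone). Their median was -0.45 (adjusted p = 3.06e-10 by camera and 0.161 with an estimated correlation). Of 14 target kinase and ligand genes 0 rose and 2 fell (2 and 7 adjusted over the list alone), while Vegfa did not pass (0.34, adjusted p = 0.0707). Their median was -0.36 (adjusted p = 0.000362 by camera and 0.167 with an estimated correlation).

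In the same livers, of 20 beta-oxidation genes 3 rose and 0 fell (9 and 0 adjusted over the list alone). Their median was 0.24 (adjusted p = 3.2e-11 by camera and 0.435 with an estimated correlation). Of 15 PPAR-alpha genes 4 rose and 0 fell (5 and 0 adjusted over the list alone). Their median was 0.14 (adjusted p = 9.71e-05 by camera and 0.553 with an estimated correlation). Of 20 ATF4 genes 1 rose and 0 fell (2 and 0 adjusted over the list alone). Their median was 0.27 (adjusted p = 0.000208 by camera and 0.646 with an estimated correlation). The cholesterol list (25 genes) had a median of 0.46, with Lss at 0.74. Adjusted p was 2.8e-08 by camera and 0.982 with an estimated correlation, and 0 members passed (0 adjusted over the list alone). Combination library 6 lay at 1.13 for this list, whose median was 0.29 without it, and Lss was at 2745 and 3531 normalised reads in combination libraries 5 and 6 against 876 to 1253 in the other 4. Without vehicle library 3 the PPAR-alpha median was 0.22, and without combination library 4 the ATF4 median was 0.17. The ribosomal protein list (25 genes) had a median of 0.14. Adjusted p was 1.44e-08 by camera and 0.982 with an estimated correlation, and 0 members passed (6 adjusted over the list alone). The matrix list (26 genes) had a median of -0.49, with Col1a1 at -0.89 (adjusted p = 0.335) and Sparc at -0.66. Adjusted p was 6.49e-09 by camera and 0.982 with an estimated correlation, and 0 members passed (0 adjusted over the list alone). In total 50 genes rose and 70 fell. The total of 120 became 56, 70, 70 and 78 without combination libraries 5, 4, 6 and 1, 62, 69, 71 and 79 without vehicle libraries 2, 3, 1 and 5, and 265 without combination library 2. The calls of Kitl, Igfbp3, Chrna4, Sesn2, Eci1, Esm1, Plin4 and Dll4 were lost without any 1 of 11, 9, 8, 7, 5, 5, 4 and 3 libraries. Those of Kitl, Sesn2, Igfbp3, Dll4 and Acot1 were lost with only these 2 groups, Igfbp3 without the 3 libraries that stood apart, Kitl with no filter or voom, and Chrna4 on log2 of normalised reads. A replicate block over all livers ended the calls of Kitl and Sesn2. In vehicle and combination livers alone, where pairing by number is only a hint, the block ended that of Sesn2 (adjusted p = 0.116) but not of Kitl (0.0343), and Vegfa passed (0.0380). There the sinusoidal list held by camera (2.64e-25) and was lost with an estimated correlation (adjusted p = 0.109).

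**Figure D4:**
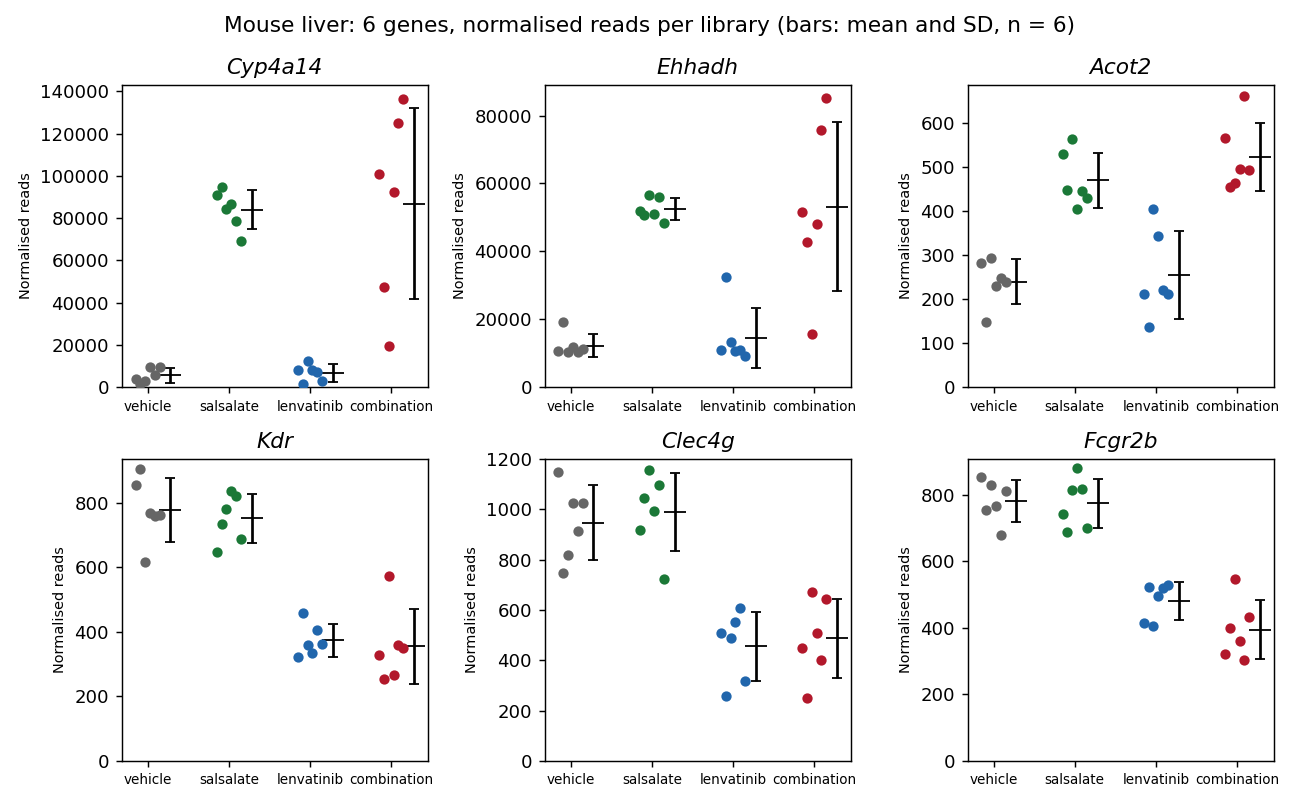
Normalised reads of 6 genes in each mouse liver library (points, n = 6 per group) by treatment, with the group mean and SD beside them. Cyp4a14 was at 5536 ± 3417 in vehicle and 84042 ± 9136 in salsalate livers, and Kdr at 778 ± 98.3 in vehicle and 374 ± 50.9 in lenvatinib livers.

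Adding salsalate to lenvatinib was compared with lenvatinib alone. Cyp4a14 (3.76 ± 0.51, adjusted p = 0.00101), Chrna4 (2.40 ± 0.43), Cyp4a31 (2.38 ± 0.32), Cyp4a10 (2.31 ± 0.39), Ehhadh (1.83 ± 0.31), the fatty acid-binding protein Fabp5 (1.52 ± 0.31), acetyl-CoA synthetase Acss2 (1.49), Acot1 (1.34), Acot2 (0.86), Acadl (0.42) and Hadha (0.32) rose. Ppp1r1b, a phosphatase inhibitor outside the naming rule that was chosen after its value was seen, fell by 0.69. Of 20 beta-oxidation genes 3 rose and 0 fell (8 and 0 adjusted over the list alone). Their median was 0.26 (adjusted p = 6.43e-13 by camera and 0.328 with an estimated correlation). Of 15 PPAR-alpha genes 4 rose and 0 fell (7 and 1 adjusted over the list alone). Their median was 0.30 (adjusted p = 1.14e-07 by camera and 0.167 with an estimated correlation). Of 25 cholesterol genes 0 rose and 0 fell (21 and 0 adjusted over the list alone), with Pmvk at 0.98 (adjusted p = 0.0731) and Dhcr7 at 0.82 (adjusted p = 0.0956), and lenvatinib library 2 lay at -0.92 and combination library 6 at 1.13 for the list. Their median was 0.77 (adjusted p = 1.55e-21 by camera and 0.338 with an estimated correlation). Without the 3 libraries that stood apart the median was 0.28. Of 20 fatty acid and triglyceride synthesis genes 1 rose and 0 fell (9 and 0 adjusted over the list alone), and lenvatinib library 2 lay at -1.53. Their median was 0.57 (adjusted p = 1.67e-08 by camera and 0.653 with an estimated correlation). That median was 0.26 without it and 0.24 without the 3. Kdr (-0.09, adjusted p = 0.841) and Trem2 (-0.54) did not pass. In total 24 genes rose and 1 fell, but with only these 2 groups in the fit limma called 0 at adjusted p under 0.05 (585 at unadjusted p under 0.05, and 16 by voom on all groups). The total of 25 was 3 (Cyp4a14, Cyp4a31 and Ehhadh) without the 3 libraries that stood apart. It was 11 and 14 without combination libraries 5 and 6, 14, 14 and 15 without vehicle libraries 5, 6 and 3, 15 and 16 without salsalate libraries 1 and 4 and without lenvatinib libraries 2 and 5 in turn, but 42 without combination library 3 and 71 without lenvatinib library 1. The calls of Acot1, Acadl, Fabp5 and Acss2 were lost without any 1 of 16, 16, 12 and 12 libraries, and those of Chrna4 and Hadha without combination library 5. Array weights ended the calls of Cyp4a10 and Acot2 too, and quantile normalisation that of Hadha.

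Adding lenvatinib to salsalate was compared with salsalate alone. Kdr fell by 0.94 ± 0.12 (SE, adjusted p = 7.5e-05), Gpihbp1 by 0.93, Clec4g by 0.93, Clec14a by 0.86, Fcgr2b by 0.84, Ptprb by 0.75, the angiopoietin co-receptor Tie1 by 0.56 and the retinoic acid-degrading enzyme Cyp26b1 by 0.97. Of 22 sinusoidal endothelial genes 0 rose and 11 fell (0 and 17 adjusted over the list alone). Their median was -0.55 (adjusted p = 4.82e-48 by camera and 0.000295 with an estimated correlation). Of 15 angiogenic genes 0 rose and 0 fell (0 and 9 adjusted over the list alone), with Dll4 at -0.63 (adjusted p = 0.0563). Their median was -0.37 (adjusted p = 1.24e-14 by camera and 0.0828 with an estimated correlation). Of 14 target kinase and ligand genes 0 rose and 1 fell (0 and 4 adjusted over the list alone). Their median was -0.28 (adjusted p = 5.41e-06 by camera and 0.0828 with an estimated correlation). The cholangiocyte list (12 genes) had a median of -0.38, with Krt19 at -0.76. Adjusted p was 8.02e-06 by camera and 0.753 with an estimated correlation, and 0 members passed (0 adjusted over the list alone). The acute phase list (20 genes) had a median of 0.24, with Crp at 0.27. Adjusted p was 0.000149 by camera and 0.900 with an estimated correlation, and 0 members passed (0 adjusted over the list alone), and the call was lost without combination library 6 (adjusted p = 0.133), whose acute phase genes lay 0.94 above its group and without which the median was 0.07. In total 0 genes rose and 41 fell, or 26 changed without combination library 5 and 96 without combination library 2. The call of Cyp26b1 was lost on log2 of normalised reads. Beside the 0, limma gave 764 genes of either direction at unadjusted p under 0.05.

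The interaction of the drugs in liver gave 0 genes with limma at adjusted p under 0.05, 371 at unadjusted p under 0.05, and 0 also by voom, quantile normalisation and median centring. Averaged over both backgrounds, 88 genes rose and 11 fell with salsalate. Beside the Cyp4a genes (3.96 for Cyp4a14, 2.43 for Cyp4a10 and 2.14 for Cyp4a31), Ehhadh (1.98) and Chrna4 (1.99), the lipid genes Pnpla3 (1.42), Acss2 (1.12), Fabp5 (1.12), Acly (0.89) and the sterol enzyme Dhcr7 (0.60) rose, while Serpina12 (-1.22), Plin4 (-1.16), the transporter Slco1a4 (-0.72) and Cfhr4 (-0.32) fell. Of 20 beta-oxidation genes 8 rose and 0 fell (13 and 0 adjusted over the list alone). Their median was 0.23 (adjusted p = 8.74e-22 by camera and 0.0896 with an estimated correlation). Of 20 fatty acid and triglyceride synthesis genes 3 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 0.36 (adjusted p = 7.47e-09 by camera and 0.639 with an estimated correlation). It was 0.23 without the 3 libraries that stood apart, of which lenvatinib library 2 lay at -1.53 for the list. The salsalate total of 99 was 56, 57, 61 and 65 without combination library 5, salsalate library 5, vehicle library 2 and salsalate library 6, and 170 without lenvatinib library 1. The calls of Dhcr7, Acly, Cfhr4 and Slco1a4 were lost without any 1 of 16, 12, 10 and 4 libraries, and without the 3 that stood apart.

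With lenvatinib 10 genes rose, led by Trib1 (0.31), Mif (0.30), Nop16 (0.24) and Dvl1 (0.21), and 107 fell, such as Clec4g (-0.94), Kdr (-0.92), Gpihbp1 (-0.89) and Cyp26b1 (-0.88). Of 22 sinusoidal endothelial genes 0 rose and 16 fell (0 and 19 adjusted over the list alone). Their median was -0.52 (adjusted p = 1.21e-52 by camera and 0.000295 with an estimated correlation). Of 15 angiogenic genes 0 rose and 7 fell (0 and 10 adjusted over the list alone), including Esm1 (-1.13), Dll4 (-0.58) and the VEGF receptor gene Flt1 (-0.35). Their median was -0.30 (adjusted p = 2.62e-13 by camera and 0.0896 with an estimated correlation). The ERK list (16 genes) had a median of 0.14. Adjusted p was 0.0338 by camera and 0.982 with an estimated correlation, and 0 members passed (0 adjusted over the list alone), a call lost without any of lenvatinib libraries 4 and 6, combination libraries 2 and 4, salsalate library 2 and vehicle library 4. The Kupffer cell list (13 genes) had a median of 0.20, or -0.004 without the 3 libraries that stood apart, 0.12 without vehicle library 4 or lenvatinib library 2 and 0.31 without lenvatinib library 1. Adjusted p was 0.0414 by camera and 0.982 with an estimated correlation, and 0 members passed (0 adjusted over the list alone), and the call was lost without those 3 together and without any 1 of lenvatinib libraries 2 and 5, vehicle libraries 4 and 5, salsalate libraries 1, 2 and 5 and combination libraries 3 and 6. Of the 103 list calls over the 8 contrasts in liver, 4 held with an estimated correlation, all in the sinusoidal endothelial list, and 84 of 100 groupings of the libraries, the real one included, called as many lists. The calls of Mif, Dvl1 and Flt1 were lost without any 1 of 14, 13 and 11 libraries, those of Mif, Dvl1 and Nop16 without the 3 that stood apart, those of Trib1, Mif and Dvl1 under quantile normalisation and that of Dvl1 with a replicate block. The lenvatinib total of 117 was 181 without lenvatinib library 6 and 184 without combination library 2. Across genes, the salsalate effects without and with lenvatinib correlated at r = 0.496 (rho = 0.305), and the lenvatinib effects without and with salsalate at r = 0.387 (rho = 0.261), which was 0.226 (rho = 0.144) without the 3 libraries that stood apart and 0.282 (rho = 0.173) without lenvatinib library 1. The 8 and 25 genes called in both moved the same way, against 0.0267 and 0.110 for independent lists, and the 8 were 3 without the 3 libraries and 13 without combination library 3.

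The effects in cells and livers were set side by side over 9409 genes matched by symbol. Of the genes called in cells, 1470 of 3042 (48.3%) had the same sign in liver for salicylate against salsalate, 1041 of 2289 (45.5%) for lenvatinib and 2495 of 5137 (48.6%) for both. Tested as directed sets in liver, these genes gave fry p = 0.307, 0.306 and 0.515, and the effects correlated across genes at r = 0.006, -0.035 and 0.049. The difference between the systems was not tested, and they also differed in species, exposure time and dose.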

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

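The tests of the Kupffer cell genes, of the endothelial pairs, and of the tumour genes and depth of lenvatinib library 2, were chosen only after the result was seen, as was the fit without 3 libraries. The pan-endothelial and sinusoid-restricted gene lists were written after the data were examined, but before their test. The endothelial permutation was extended to every regrouping, and its reading rule widened, after a first p on the same side of 0.05 was known.

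The sinusoidal list was lower in the 12 livers given lenvatinib, also without the 3 libraries that stood apart (adjusted p = 0.00128 with an estimated correlation). A lower share of non-parenchymal cells of every type was argued against by the Kupffer cell list at a median of 0.20 (-0.004 without those 3) beside -0.52 for the sinusoidal list, but matrix (-0.30), cholangiocyte (-0.24) and stellate (-0.18, or -0.05 without those 3) lists lay below 0, so a lower share of some types stays open. A loss of endothelial cells of every kind stays open: 15 pan-endothelial genes changed by -0.61 (exact permutation p = 9.37e-06) and 12 sinusoid-restricted genes by -0.80 (2.34e-06, the smallest that the 853776 regroupings within each background allow), with an exact permutation p of 0.0574 for the difference of -0.20. Between paired combination and vehicle livers the difference was -0.13, lower in 5 of 6 pairs (exact p = 0.0625 over 64 changes of sign). Lower expression per cell cannot be told apart from fewer cells, as cell numbers were not measured.

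Lenvatinib library 2 lay apart from the other livers, with Tff3 at 9397 normalised reads against a mean of 244 in the other lenvatinib livers and Cyp2e1 at 11759 against 130110. Low depth was argued against by 27.9 M reads (21.4 to 25.6 in the others), and a missed lenvatinib treatment by a sinusoidal list mean of 8.73, within the 8.56 to 9.09 of the other 11 treated livers and below the 9.22 to 9.44 of the untreated, although Esm1 (194.6 normalised reads) and Dll4 (75.4) lay within the vehicle range. Tumour or lesion tissue may be the source but is not decided: the tumour and progenitor list lay at 0.74, above the other lenvatinib livers (-0.67 to 0.54) and below combination library 2 (0.85). A periportal piece of the lobule is not decided either, as the periportal list lay at 0.46 with the others at -0.64 to 1.33, and other differences between animals were not tested.

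In cells the ATF4 list exceeded the sum of the single compounds by a mean of 0.15. Flattening of low values was argued against by a mean of 0.15 on log2 of normalised reads (20 of 21 members above 0). Greater depth of the combination libraries was argued against by 0.16 after thinning every library to equal reads (21 of 21 members above 0), and both passed fry. A hypothesis, found and tested on the same 12 libraries, is that the ATF4 response to both is more than additive on a log2 scale.

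Other splits of the libraries were refitted. For the 5 pairs of cell groups the 10 splits are too few for a share under 0.05, with 3755, 2819, 6409, 4161 and 3772 genes in the real splits and at most 0 in any of the others. Chance was excluded for the salicylate (1 of 100 groupings, 5782 genes against at most 1113) and lenvatinib (1, 4823 against 95) main effects in cells. It stays open for the interaction (3, 130 against 3228), into which regrouping carries main effects, and for the lists called (2, 91 against 91). So it does for the salicylate (2, 0.736 against 0.797) and lenvatinib correlations (2, 0.752 against 0.799), passed in another grouping. In liver it was excluded for salsalate (1, 15 genes against 0), both drugs against salsalate (1, 41 against 19), the lenvatinib main effect (1, 117 against 1), and both drugs against vehicle with the replicate block (1 of the 32 splits that part all 6 pairs, 128 against 1, the others mixing both treatments on each side). Chance stays open for lenvatinib (2, 37 against 376), both drugs (2, 120 against 543) and the salsalate main effect (2, 99 against 1377). So it does for the salsalate correlation (2, 0.496 against 0.659). Splits calling several times the real count point to a structure of the samples. Nor was chance excluded for both drugs against lenvatinib (5, 25 against 1031), the interaction (100, 0 against 290), the lists called (84, 103 against 178) and the correlation of lenvatinib effects (6, 0.387 against 0.504). The same-sign shares between cells and liver lay 1.68, 4.52 and 1.43 percentage points from 50% for salicylate, lenvatinib and both, and 54, 47 and 61 of 100 splits lay as far (at most 6.74, 10.1 and 6.34), so chance was not excluded.

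Single libraries lay far from the other 5 of their group in 22 of 288 groups, where chance gives about 14.4. Combination library 5 held 6.64% mitochondrial reads, and combination library 2 scored -11.7 on principal component 2. On the variance-stabilised scale, vehicle library 2 was low in Acot2 (7.93) and high in Ehhadh (14.24), Esm1 (8.76) and Igfbp3 (10.31), vehicle library 3 low in Ptprb (10.19) and high in Sesn2 (8.54), and vehicle library 4 low in Col1a1 (10.43). Lenvatinib library 2 was high in Ehhadh (14.99) and Esm1 (8.19) and low in Insig1 (12.27), Pmvk (9.10) and Ptprb (9.03), and lenvatinib library 1 high in Atf4 (11.61). Salsalate libraries 4, 1 and 5 stood out for Bmp2 (9.15, high), Eci1 (12.12, low) and Hadha (13.82, high). Combination library 2 was high in Krt19 (9.00) and Mif (12.20), and library 3 low in Hadha (13.54) and high in Oit3 (9.45).

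The salicylate effect in cells differed with lenvatinib present, by the interaction test, for PABPC1L (0.52), MT1G (0.51), AKNA (0.46), SH3BP2 (0.39), PCK2 (0.31), PHGDH (0.30), SLC3A2 (0.20), TNFSF4 (-0.55), LFNG (-0.53), FOXJ1 (-0.50), LCN10 (-0.47), PLIN2 (-0.43) and CCL20 (-0.37). Of 81 lists and treatments compared, 3 moved one way in every treated liver and the opposite way in every treated cell library, and these differences were not tested. They were oxidative phosphorylation with salsalate (0.077 in liver, -0.07 in cells), and DNA replication (0.14, -0.02) and ribosomal proteins (0.15, -0.12) with both drugs.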

How the results depend on the processing

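The fit without 3 mouse libraries together (lenvatinib 2 and 5, combination 6), the fit of 2 paired groups and list medians without libraries were chosen after seeing the data. No named call changed direction in any setting run. Of named genes not called, Glul for lenvatinib turned without the 3 libraries (0.13), Kdr for both against lenvatinib with array weights (0.03) and DUSP6 without cell lenvatinib library 1 (0.0026). Of 202 named calls in cells 194 held without any 1 library, and of 86 in liver 59 did, with 69 kept without the 3 libraries, 80 with array weights and 81 with the replicate block. Of 91 list calls in cells and 103 in liver, 74 and 48 held without any 1 library, and 81 and 17 with fry. The other numbers below are counts of genes called, and the cause was not tested unless fewer genes or libraries are named. Of the smallest changes simulated, 26% were called for lenvatinib against vehicle in liver, a share in which depth, the floor, the spread between animals and their number were not separated.

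The interaction in cells, 130, was 61 with no filter (more genes tested), 22 with no variance trend, 219 with median centring, 466 with array weights and 236 with the replicate block. Leaving out 1 library gave 33 (combination 3) to 781 (lenvatinib 2). In liver, array weights gave 87 for salsalate (15), 281 for both drugs (120), 118 for both against salsalate (41), 218 for the salsalate main effect (99) and 224 for the lenvatinib main effect (117). With only the 2 groups, and so fewer libraries, salsalate gave 60, both drugs 51 and both against lenvatinib 0 (25 with all groups), for which limma gave 585 at unadjusted p under 0.05. The last comparison gave 14 with no filter, 38 with the replicate block, 16 with voom and 3 without the 3 libraries, and salsalate 28 without them. Leaving out 1 library gave 9 (vehicle 2) to 25 (lenvatinib 2) for salsalate, 30 (vehicle 1) to 60 (lenvatinib 6) for lenvatinib, 56 (combination 5) to 265 (combination 2) for both drugs, 11 (combination 5) to 71 (lenvatinib 1) for both against lenvatinib, 26 (combination 5) to 96 (combination 2) for both against salsalate, 56 (combination 5) to 170 (lenvatinib 1) for the salsalate main effect and 98 (salsalate 6) to 184 (combination 2) for the lenvatinib main effect.

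With an estimated correlation 15 list calls were left in cells and 4 in liver, where fry left 17. Lists whose direction turned are given by adjusted p. Without the 3 libraries these were, for lenvatinib, interferon 0.0175, stellate 0.633, pericentral 0.00422 and periportal 0.00251. For both drugs against lenvatinib they were ribosomal 0.1004, Kupffer 0.00415 and pericentral 0.000136, and for the interaction fatty acid synthesis 0.544, ribosomal 2.37e-05 and pericentral 0.00262. In the main effects they were pericentral for salsalate 0.00594 and Kupffer for lenvatinib 0.944. Array weights turned the pericentral list for lenvatinib (0.457). Leaving out 1 library turned mitochondrially encoded transcripts in the cell interaction (5.55e-08 without lenvatinib 2 to 0.973 without lenvatinib 1), the pericentral list for lenvatinib (0.00273 without lenvatinib 4 to 0.213 without lenvatinib 2) and for both against lenvatinib (0.0158 without lenvatinib 4 to 0.373 without combination 1), the acute phase list for both against lenvatinib (0.000986 without combination 5 to 0.905 without combination 6) and the cholesterol list for both against salsalate (1.00e-05 without combination 4 to 0.963 without combination 6).

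The block changed no other count by over 1.5 times. Blocking the vehicle and combination livers by number gave 128 genes (52 higher, 76 lower), of which 76 were among the 120, and of the list calls by camera it lost YAP and TGF-beta (0.0715) and gained 5 others. In other groups the numbers did not pair the libraries. Every cell library of vehicle and salicylate (0.0213 to 0.0970) and of vehicle and lenvatinib (0.0485 to 0.124) correlated best with its own number, a hint from the data only.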

Other observations

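Values without libraries in this part were added after seeing the data, and the lists described were picked with their values in view. Further lists in liver were averaged over both backgrounds. With salsalate, of 25 cholesterol genes 1 rose and 0 fell (19 and 0 adjusted over the list alone), with Fdps at 0.89 (adjusted p = 0.0722) and Pmvk at 0.66 (adjusted p = 0.0522). Their median was 0.49 (adjusted p = 1.34e-18 by camera and 0.456 with an estimated correlation). It was 0.32 without the 3 libraries that stood apart, of which lenvatinib library 2 lay at -0.92 and combination library 6 at 1.13 for the list. Of 15 periportal and gluconeogenic genes 0 rose and 0 fell (0 and 4 adjusted over the list alone), with the serine dehydratase Sds at -0.90 (adjusted p = 0.152). Their median was -0.33 (adjusted p = 2.78e-05 by camera and 0.653 with an estimated correlation). It was -0.17 without those 3, of which lenvatinib libraries 5 and 2 lay at 1.33 and 0.46, with Sds at 18268 and 13157 normalised reads against 1925 to 7235 in the other 4 of their group. The matrix list (26 genes) had a median of -0.30 with lenvatinib, Sparc being at -0.44 (adjusted p = 0.320). Adjusted p was 2.28e-06 by camera and 0.982 with an estimated correlation, and 0 members passed (0 adjusted over the list alone).

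Immune and bile duct marker lists were also compared. The T and NK cell list (10 genes) had a median of 0.23 in livers given salsalate against vehicle, with the T cell receptor subunit Cd3e at 0.28. Adjusted p was 0.00148 by camera and 0.982 with an estimated correlation, and 0 members passed (0 adjusted over the list alone). The B and plasma cell list (9 genes) lay at -0.26 with both drugs against salsalate, with the B cell receptor subunit Cd79b at -0.38, and Cd79b had a lenvatinib main effect of -0.26 (adjusted p = 0.138). Adjusted p was 0.00337 by camera and 0.982 with an estimated correlation, and 0 members passed (1 adjusted over the list alone). The cholangiocyte list (12 genes) lay at -0.24 in the lenvatinib main effect. Adjusted p was 0.00135 by camera and 0.982 with an estimated correlation, and 0 members passed (0 adjusted over the list alone).

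A hypothesis was that livers with more matrix transcripts also hold more transcripts of recruited macrophages, whatever their treatment. Over the 24 livers, the deviations of the 2 list means (26 and 14 genes) from their group means correlated at r = 0.787 (permutation p = 8.00e-05) and rho = 0.777 (permutation p = 1.00e-04), with 100000 permutations and 1 relation tested (adjusted p the same). Without combination library 2 and lenvatinib library 6, whose matrix deviations from the group mean lay farthest from the median deviation, they were r = 0.736 (permutation p = 0.00153) and rho = 0.710 (permutation p = 9.70e-04). These data may reflect the extent of injury in the piece sampled, which was not measured.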
